A study of Mus musculus with 16 samples.

How the data were processed

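RNA was measured by sequencing in dissociated lumbar dorsal root ganglia of mice, the ganglia that hold the cell bodies of sensory neurons. One sciatic nerve was crushed, and injured and naive ganglia were taken from each animal 24 h or 72 h later. The 16 libraries fall into 4 groups of 4: injured and naive at 24 h, and injured and naive at 72 h. Per the labels, the ganglia were lumbar L4 to L6, were dissociated with a Percoll step, and gave total RNA for TruSeq libraries. The series text counts 4 mice at each time as its replicates, but the labels do not say which injured and naive libraries came from the same animal, so the comparisons were unpaired. All sample descriptions carry the same date, so the labels give no batch for a library.

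Both deposited tables hold counts, that is, whole read counts that the authors did not scale. The submitters' processing notes name bcl2fastq 2.17, STAR and HTSeq and the builds GRCm38 and mm10. They give no strand setting, no annotation release and no rule for reads that map to several places. The gene table has 48795 Ensembl genes, of which 48349 matched a symbol in the reference table of gene names. The other deposited table gives counts for 205758 short genomic windows, 92.5% of them 24 bp long and the longest 148 bp, each named by position and by a repeat family or by none. How the windows were chosen is not stated. Of these windows, 169064 carried a family, among them 56580 B2, 55655 Alu (the mouse B1 elements) and 18204 L1 windows. The 36694 windows without a family held 71.2% of the counts of that table and were set aside from the repeat tests. As a check of the build, 97.45% of the windows that the file annotates as exon or 3' UTR lay inside GENCODE exons, against 21.8% of all windows. The 72 h columns of both tables carry no time in their names and were assigned to 72 h by elimination.

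Counts per library ranged from 32758978 to 56484541 in the gene table and from 522869 to 899167 in windows with a repeat family. Within groups, no pair of libraries was close enough to be a duplicate: chi-square per degree of freedom was at least 9.85. Intervals and floors given here cover counting error only, since reads without molecular identifiers are not independent molecules.

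Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group (minimum count 10, minimum total 15), quasi-likelihood fits of all 16 libraries with group as the only term, and Benjamini-Hochberg adjustment at 0.05. This left 19151 genes. The comparisons were injured against naive at 24 h, injured against naive at 72 h, the difference between these responses (72 h minus 24 h), and naive 72 h against naive 24 h. Standard errors were the absolute log2 fold change divided by the square root of F. Log2 CPM used a prior count of 2. Repeat windows, called loci, were tested the same way with the library sizes and TMM factors of the gene table, so that a broad change of repeats would not be scaled away. Of these, 3780 loci passed the filter, and 37 families were tested on counts summed over their windows. Summed B2 CPM over scaled gene counts were compared with an exact 2-sided permutation test of 4 against 4 libraries, which cannot give a p below 0.0286. The share of B2 among rising loci was compared with that among all other tested loci by Fisher's exact test. Loci were placed in exons, introns or outside genes with GENCODE M21 and bedtools 2.31.1.

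Before the data were examined, 22 gene lists and their members were fixed, together with the tests, the alternatives and the rule for named genes. The lists covered regeneration transcription factors, regeneration-associated effectors, sensory neuron identity, voltage-gated and background ion channels, the integrated stress and unfolded protein response, cholesterol synthesis, immediate-early and heat-shock genes, the interferon response, inflammatory cytokines and chemokines, retrotransposon silencing, RNA polymerase III machinery, ribosome biogenesis, proliferation, and markers of satellite glia, myelinating Schwann cells, macrophages, neutrophils, lymphocytes, endothelium, mural cells, fibroblasts and erythroid cells. Lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 22 lists. A list of 20 pan-neuronal genes was written before its test. List levels are the mean log2 CPM over a list's members. Named genes are, per injury comparison, the 8 largest rises and the 6 largest falls among genes past the threshold with a mean log2 CPM of at least 2, an assigned gene name and no overlap between injured and naive libraries, plus the 3 members of each described list with the smallest p and the 4 of each sign with the smallest p for the difference of responses. Some genes that meet these rules are not reported here. Named loci had a mean of at least 10 counts and no overlap: the 4 largest B2 rises, the 2 largest B2 falls and the 2 largest of each direction in other families. A fold against libraries without any count is given as a lower bound from a floor of 3 counts over the group. This bound leaves out the error of the injured counts and the spread between libraries.

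Alternatives changed 1 choice at a time: relative log expression size factors, no filter on low counts, DESeq2 1.42.0, only the groups compared, the replicate number as a block, scaling of the repeat table by its own factors, other count minimums, B2 without its 10 most counted windows, an estimated correlation, and leaving out each library. After the data were seen, a covariate of erythroid and neutrophil marker level, B2 counts relative to repeat counts without rRNA windows, B2 windows outside exons, and leaving out each library for the lists, the overlap and the B2 share were added. The pipeline was tested on simulated data with known folds. At a true fold of 2, the gene test recovered 70.1% of 67 changed genes at 24 h, 65.7% at 72 h and 64.2% for the difference of responses, and at a fold of 4 it recovered 80.3%, 77.3% and 74.2%. The loci test recovered 28.4% of 67 changed loci at 24 h and 10.4% at 72 h at a fold of 2, and 63.6% and 65.2% at a fold of 8. Wrong calls made up between 2.17% and 10.7% of the calls. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.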

Results

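RNA was sequenced from mouse dorsal root ganglia at lumbar levels L4 to L6, which were dissociated with a Percoll step. The sciatic nerve had been crushed, which cuts the axons of many neurons in these ganglia. Injured and naive ganglia were compared at 24 h and at 72 h, with 4 libraries in each of the 4 groups. Gene counts per library ranged from 32758978 to 43229939 in injured and 41241516 to 56484541 in naive libraries at 24 h. At 72 h they ranged from 38530738 to 49717456 and from 38358039 to 54980782. Windows with a repeat family held 522869 to 899167 counts per library, of which B2 windows held 28845 to 76638. B2 is a family of short retrotransposons (SINEs) with many copies in the mouse genome. Coordinates are those of mm10 (GRCm38).

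The 24 h comparison asks which genes respond on the day after the crush. Gpr151, an orphan G protein-coupled receptor (ENSMUSG00000042816, chromosome 18, 42577881 to 42579652), went from 0.607 ± 0.125 to 24.2 ± 8.47 CPM (SD, n = 4 libraries), a log2 fold change of 5.32 (SE 0.27, adjusted p = 1.57e-12). Npy, neuropeptide Y (ENSMUSG00000029819), rose by 5.25 on the log2 scale (SE 0.39) and had only 1 to 58 counts in the naive libraries. Procr, the endothelial protein C receptor, rose by 4.10 (SE 0.17), Fst, the activin-binding follistatin, by 3.92 (SE 0.20), and Star, which carries cholesterol into mitochondria, by 3.75 (SE 0.18). Gadd45a, a growth arrest and DNA damage gene, rose by 3.28 (SE 0.10) and Flrt3, a membrane adhesion protein, by 3.26 (SE 0.12). Among genes that met the naming rule (well expressed, named and with no overlap between groups), the largest falls were smaller: Islr2 (log2 fold change −1.21, SE 0.24), the nicotinic receptor subunit Chrna6 (−1.12, SE 0.14), the transcription factors Scx (−1.03, SE 0.17) and Grhl3 (−1.02, SE 0.14), Vwc2l (−1.01, SE 0.08) and the somatostatin receptor Sstr2 (−0.996, SE 0.21). By edgeR, 2049 of 19151 genes rose and 1592 fell, and 456 and 70 of these changed by at least 1 on the log2 scale.

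Among the lists at 24 h, regeneration genes rose together. Of 44 measured regeneration-associated effectors, 34 rose and 0 fell (36 and 1 adjusted over the list alone; adjusted p = 0.000759 with an estimated correlation), with a median log2 fold change of 1.95; Gadd45a, Flrt3 and the neurotrophin gene Bdnf (1.76, SE 0.08) had the smallest p. Of 28 regeneration transcription factors, 18 rose and 0 fell (19 and 0 adjusted over the list alone; adjusted p = 0.00169 with an estimated correlation), led by Sox11 (2.83, SE 0.09), Atf3 (2.31, SE 0.09) and Klf6 (1.24, SE 0.06). Of 26 genes of the integrated stress and unfolded protein response, 15 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.0124 with an estimated correlation), among them Chac1 (1.31, SE 0.13), Ppp1r15a (0.63, SE 0.08) and the chaperone Hspa5 (0.43, SE 0.05).

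Interferon response genes were higher in injured ganglia at 24 h. Of 33 measured, 24 rose and 1 fell (25 and 1 adjusted over the list alone), with a median log2 fold change of 0.74, although the list as a whole was not called with an estimated correlation (adjusted p = 0.0946). Ifit1, an interferon-induced RNA-binding protein, rose by 1.96 (SE 0.17), Stat2, a transducer of type I interferon signals, by 0.82 (SE 0.06), and Eif2ak2, the kinase PKR that senses double-stranded RNA, by 0.63 (SE 0.08). Marker levels of macrophages (log2 difference −0.02, SE 0.28) and neutrophils (−0.26, SE 0.42) did not pass the exact permutation test at 24 h (p = 1 and p = 0.6, n = 4 per group), nor did that of lymphocytes (0.36, SE 0.28, exact permutation p = 0.229). Of 23 inflammatory cytokines and chemokines, 6 rose (8 adjusted over the list alone; adjusted p = 0.54 with an estimated correlation), including Csf1, the growth factor of macrophages and microglia (2.47, SE 0.14), Il6 (2.60, SE 0.34) and Il1a (3.08, SE 0.79); without injured 24 h replicate 3, injured 24 h replicate 4 or naive 24 h replicate 4, 4 rose.

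Sensory identity and ion channel genes changed in both directions at 24 h. Of 42 sensory neuron identity genes, 14 fell and 4 rose (17 and 5 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation). The adrenergic receptor gene Adra2c fell by 0.90 (SE 0.09) and the transcription factor gene Isl1 fell by 0.44 (SE 0.06), while the receptor gene Ret rose by 0.40 (SE 0.06). Of 44 voltage-gated and background ion channel genes, 16 fell and 6 rose (21 and 7 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation). The calcium channel subunit gene Cacna2d2 fell by 0.69 (SE 0.10), while Kcnq3 rose by 0.56 (SE 0.08).

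The 72 h comparison asks the same of the later time. Npy was 7.27 above naive on the log2 scale (SE 0.37) and Gpr151 6.21 (SE 0.26). Car3, a carbonic anhydrase (ENSMUSG00000027559, chromosome 3, 14863512 to 14872523), went from 2.41 ± 0.594 to 106.9 ± 14.4 CPM (SD, n = 4 libraries), a log2 fold change of 5.48 (SE 0.17, adjusted p = 1.84e-16). Fst rose by 4.99 (SE 0.20), Nts, the precursor of neurotensin, by 4.81 (SE 0.15), Star by 4.78 (SE 0.18), Lmo7 by 4.36 (SE 0.20) and Gal, the precursor of galanin, by 4.14 (SE 0.20). Among the falls, Comp, a cartilage matrix protein gene, fell by 1.499 (SE 0.20), Tpd52l1 fell by 1.46 (SE 0.15), Oprd1, the delta opioid receptor gene, fell by 1.30 (SE 0.12), Lin7b fell by 1.30 (SE 0.17), Vstm2b fell by 1.30 (SE 0.25) and Kcnmb1, a subunit of calcium-activated potassium channels, fell by 1.25 (SE 0.12). By edgeR, 2755 genes rose and 2577 fell, 651 and 164 of them by at least 1 on the log2 scale.

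Both regeneration lists were called higher at 72 h as well. Of 44 effectors, 42 rose and 0 fell (42 and 0 adjusted over the list alone; adjusted p = 0.000252 with an estimated correlation), with a median of 2.32. Of 28 regeneration transcription factors, 16 rose and 3 fell (16 and 3 adjusted over the list alone; adjusted p = 0.0144 with an estimated correlation), again led by Sox11 (3.13, SE 0.09), Atf3 (2.52, SE 0.09) and Klf6 (1.09, SE 0.06); 1 fell without injured 72 h replicate 2 or naive 72 h replicate 1. Stress response genes rose in 14 of 26 and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.0144 with an estimated correlation), with Chac1 at 2.02 (SE 0.13), the mitochondrial folate enzyme Mthfd2 at 1.03 (SE 0.08) and the asparagine synthetase Asns at 0.55 (SE 0.05). Of 24 cholesterol synthesis genes, 14 rose and 2 fell (15 and 3 adjusted over the list alone; adjusted p = 0.435 with an estimated correlation), among them Hsd17b7 (1.73, SE 0.09) and Insig1 (0.47, SE 0.06), against 7 and 0 at 24 h; 0 fell without naive 72 h replicate 1.

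Ion channel genes fell broadly at 72 h. Of 44, 35 fell and 3 rose (36 and 3 adjusted over the list alone; adjusted p = 0.00375 with an estimated correlation), with a median log2 fold change of −0.53. The potassium channel gene Kcna2 fell by 0.95 (SE 0.06), and the sodium channel genes Scn10a and Scn4b, which serve firing of nociceptors and resurgent current, fell by 0.86 (SE 0.07) and by 0.60 (SE 0.05). Of 42 sensory neuron identity genes, 27 fell and 5 rose (27 and 5 adjusted over the list alone; adjusted p = 0.0703 with an estimated correlation). The serotonin receptor gene Htr3a fell by 1.02 (SE 0.08), the nociceptor receptor gene Mrgprd fell by 1.00 (SE 0.09) and Adra2c fell by 0.96 (SE 0.09). Beside these falls, 20 pan-neuronal genes had a level change of −0.08 (SE 0.02), with 7 lower and 3 higher.

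Single macrophage markers rose and single neutrophil markers fell at 72 h, but neither list level passed the exact permutation test (p = 0.0571 and p = 0.171, n = 4 per group). Of 24 macrophage markers, 8 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 0.723 with an estimated correlation), with a median of 1.00; the complement gene C1qa rose by 1.99 (SE 0.24), Mrc1 by 1.22 (SE 0.21) and Csf1r by 1.58 (SE 0.29). Of 13 neutrophil markers, 8 fell (10 adjusted over the list alone; adjusted p = 0.732 with an estimated correlation), with Ltf at −1.40 (SE 0.39), Ngp at −1.40 (SE 0.42) and Camp at −1.34 (SE 0.40). That neutrophil count rested on single libraries: it was 0 without naive 72 h replicate 4, 1 without injured 72 h replicate 2, and 3 without injured 72 h replicate 1 or naive 72 h replicate 3. Neutrophil levels ranged from 1.91 to 3.88 in naive and from 0.57 to 2.42 in injured 72 h libraries (mean log2 CPM). These markers also had a higher median in naive libraries at 72 h than at 24 h, by 1.27 on the log2 scale. That list was not called with an estimated correlation either (adjusted p = 0.275). A fall in injured ganglia and a higher naive level at 72 h cannot be told apart by these values.

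**Figure D1:**
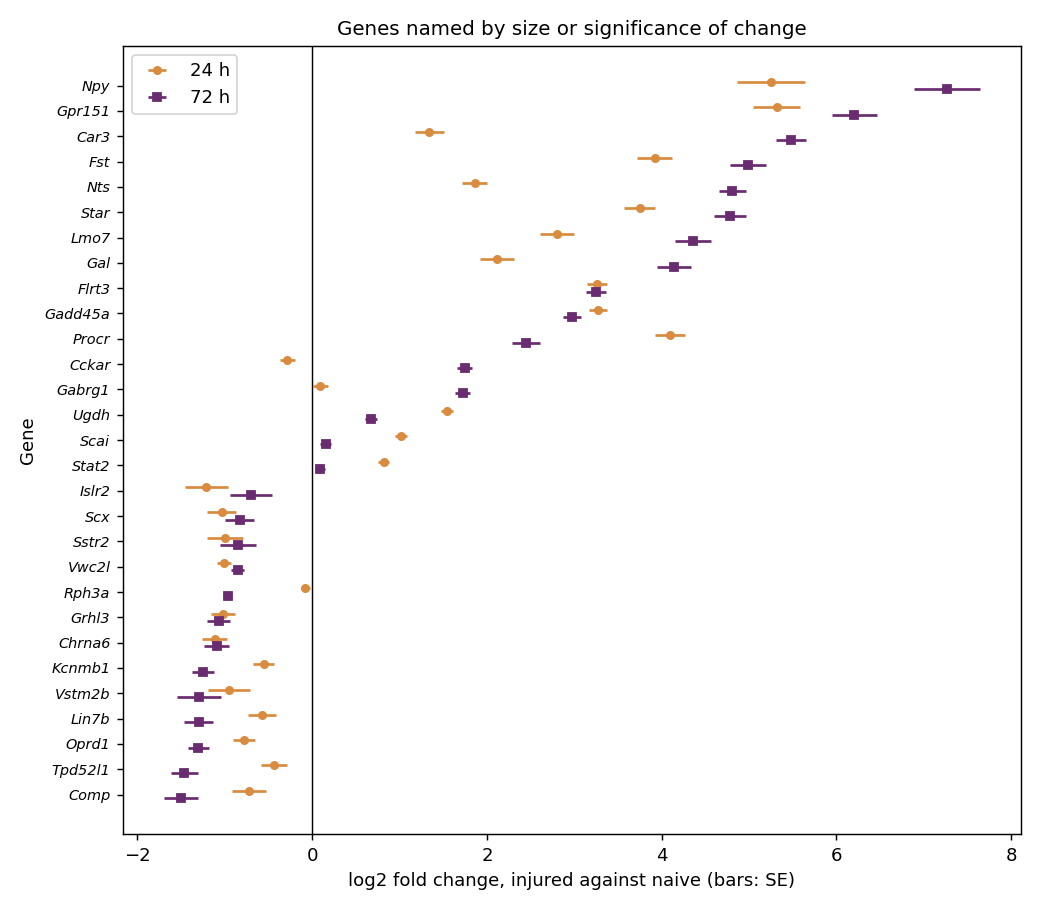
Fitted log2 fold change (injured against naive, x axis) of genes chosen by size or significance of change (y axis), at 24 h (circles) and 72 h (squares), with bars of 1 SE and 4 libraries per group. Car3 moved from 1.34 at 24 h to 5.48 at 72 h, Procr from 4.10 to 2.45.

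Most early changes were present at 72 h too. Of the genes that rose at 24 h, 1322 (64.5%) also rose at 72 h, against 294.8 for independent lists. Of those that fell, 1028 (64.6%) also fell, against 214.2, so the shares were near equal without a minimum fold. A further 47 genes went in opposite directions. Among genes changed by at least 1 on the log2 scale, 320 were shared in the same direction: 304 of the 456 rises at 24 h (66.7%) but 16 of the 70 falls (22.9%).

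The difference between the responses shows what grew or faded from 24 h to 72 h. Car3 gained 4.14 on the log2 scale (SE 0.23, adjusted p = 1.76e-10), Nts 2.95 (SE 0.20), Cckar, a cholecystokinin receptor, 2.03 (SE 0.12, from −0.28 to 1.75), and Gabrg1, a GABA receptor subunit, 1.63 (SE 0.12, from 0.10 to 1.72). The rabphilin gene Rph3a went from −0.08 to −0.97 (difference −0.89, SE 0.07), Scai from 1.02 to 0.16 (difference −0.86, SE 0.09), Ugdh, a UDP-glucose dehydrogenase gene, from 1.55 to 0.68 (difference −0.87, SE 0.10), and Stat2 from 0.82 to 0.09 (difference −0.73, SE 0.08). By edgeR, 548 genes had a more positive response at 72 h and 659 a more negative one. Of these 1207 genes, 344 with a more positive response were called higher at 72 h and had a 24 h log2 fold change above 0. Another 267 with a more negative response were called lower at 72 h and had a 24 h value below 0. Neither set of genes had to be called at 24 h. Of 238 that rose at 24 h and stood lower at 72 h, 104 were still above naive and 134 at or below it, and of 59 that fell at 24 h and stood higher at 72 h, 12 were still below naive and 47 at or above it. The others met none of these definitions.

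Between the times, the ion channel list was the 1 list that passed with an estimated correlation. Of 44 ion channel genes, 20 had a lower response at 72 h and 1 a higher one (28 and 1 adjusted over the list alone; adjusted p = 0.0108 with an estimated correlation), with Kcna2 at −0.72 (SE 0.09), the calcium channel subunit Cacnb4 at −0.63 (SE 0.08) and Scn10a at −0.70 (SE 0.10). Of 44 effectors, 22 had a higher response and 3 a lower one (25 and 4 adjusted over the list alone; adjusted p = 0.0717 with an estimated correlation), among them Nts, Cacna2d1 (1.06, SE 0.09) and the growth cone protein gene Gap43 (1.14, SE 0.13). Of 33 interferon response genes, 16 had a lower response and 0 a higher one (20 and 0 adjusted over the list alone; adjusted p = 0.0672 with an estimated correlation); Ifit1 differed by −1.87 (SE 0.24) and the RNA sensor gene Ddx58 by −0.72 (SE 0.11), and 10 were lower without injured 72 h replicate 2. At 72 h itself, 1 interferon gene rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.985 with an estimated correlation). Of 42 sensory identity genes, 7 were lower and 1 higher (10 and 3 adjusted over the list alone; adjusted p = 0.517 with an estimated correlation), with Trpa1, an irritant channel, at −0.82 (SE 0.13).

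**Figure D2:**
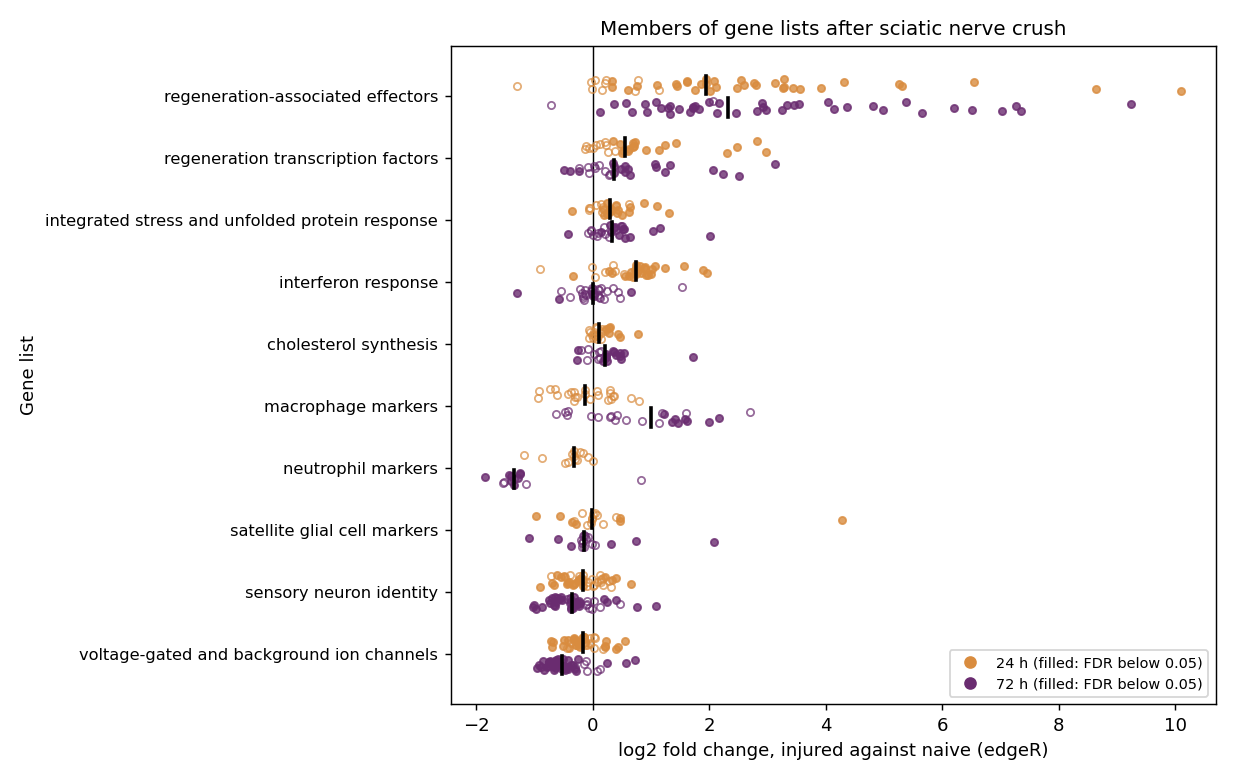
Log2 fold changes (x axis, injured against naive, edgeR) of the members of 10 gene lists (y axis) at 24 h (orange) and 72 h (purple). Each circle is a gene, filled where it passed the threshold, and the vertical bar is the list's median, such as 0.74 and 0.01 for the interferon response at 24 h and 72 h.

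The naive libraries of the 2 times show how far the control ganglia differed between 24 h and 72 h. These ganglia came from the animals with the crush and the labels give no batch, so the cause of a difference cannot be told. Marker lists of blood, cycling and vessel cells had higher medians at 72 h: neutrophils 1.27, erythroid cells 0.97, mural cells 0.48, proliferation 0.46 and endothelium 0.36. None of these 5 lists passed with an estimated correlation (adjusted p = 0.275, 0.34, 0.144, 0.275 and 0.239), and without naive 72 h replicate 4 the neutrophil, erythroid, mural and proliferation medians were 0.81, 0.67, 0.19 and 0.22. Of 13 neutrophil, 6 erythroid and 25 proliferation genes, 1, 0 and 2 were higher by edgeR (7, 1 and 9 adjusted over the list alone). DESeq2 called 1, 0 and 4, and 4 erythroid genes had an unadjusted p under 0.05. Without naive 24 h replicate 2 the edgeR counts were 3, 2 and 4, and without naive 72 h replicate 4 they were 0. Among vessel wall genes, Myh11, smooth muscle myosin, rose by 1.53 (SE 0.17), Acta2 by 0.90 (SE 0.15) and Tagln by 0.76 (SE 0.19), which are 3 of 9 mural markers (5 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation). Of 14 endothelial markers, 4 rose (8 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation), led by Cdh5 (0.82, SE 0.14), Tie1 (0.77, SE 0.13) and Flt1 (0.56, SE 0.11); 8 rose without naive 24 h replicate 1. Of 33 interferon response genes, 1 rose, Rsad2, by 1.08 (SE 0.16) (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.275 with an estimated correlation). By edgeR, 308 genes were higher and 140 lower at 72 h, fewer than for either injury comparison. This count of 448 was 265 without naive 24 h replicate 3, 285 without naive 24 h replicate 4, and 188, 200 and 170 without naive 72 h replicates 1, 2 and 3, and it was 948 by DESeq2 and 1168 with no filter on low counts.

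Repeat loci were tested to ask where in the genome repeat RNA changes after the crush, as the series title names B2 at specific loci. B2 loci rose at both times and very few fell. At 24 h, 93 of 886 tested B2 loci rose (10.5%) and 0 fell by edgeR (DESeq2 called 147 higher and 3 lower, and 247 B2 loci had an unadjusted p under 0.05). At 72 h, 222 B2 loci rose (25.1%) and 3 fell. Among the 2894 tested loci of other families, 82 rose at 24 h (2.83%) and 121 at 72 h (4.18%), so the odds that a tested locus rose were 4.02 times higher for B2 at 24 h (95% interval 2.92 to 5.54, Fisher's exact p = 2.74e-18) and 7.66 times higher at 72 h (6.01 to 9.79, Fisher's exact p = 1.5e-66). Of the Alu loci, 18 of 683 rose at 24 h and 40 at 72 h; of the L1 loci, 10 and 9 of 255 rose. Loci are not independent replicates.

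The rising B2 loci lay in introns and outside genes. At 72 h, 98 of 307 tested intron B2 loci rose (31.9%; odds ratio 6.74, Fisher's exact p = 1.65e-21) and 115 of 355 outside genes (32.4%; odds ratio 7.24, Fisher's exact p = 1.51e-24), but 9 of 224 in exons (4.02%; odds ratio 1.40, Fisher's exact p = 0.405). At 24 h the counts were 40 in introns, 50 outside genes and 3 in exons. The rising B2 loci had a median log2 fold change of 4.67 at 24 h and 3.64 at 72 h, or 3.98 and 3.61 with the 35 and 26 loci that had no naive count at their lower bound. All tested B2 loci had medians of 0.68 and 1.24, against 0.11 for all tested loci at both times. Over all families, 175 loci rose and 21 fell at 24 h, and 343 rose and 66 fell at 72 h. With the repeat table scaled by its own factors, 142 and 33 did so at 24 h and 288 and 122 at 72 h, as the median of all tested loci moved to 0.02 and −0.05 and that of B2 loci to 0.59 and 1.06.

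These counts of loci depended on single libraries and on the model. The 196 loci at 24 h were 97 without injured 24 h replicate 4 and 121 without naive 24 h replicate 2, and the 93 rising B2 loci were 42 and 56. The 409 loci at 72 h were 248 without injured 72 h replicate 2, 259 and 252 without naive 72 h replicates 1 and 2, and 219 with the erythroid and neutrophil marker level as a covariate, which was added after the data were seen. The 222 rising B2 loci were 132, 134, 135 and 109 in these fits. B2 odds ratios in those fits were 3.28 and 3.13 at 24 h, and 5.88, 4.99, 5.13 and 4.996 at 72 h. With all loci of at least 10 counts in total (21391 tested, 7918 of them B2), 118 and 228 B2 loci rose and the odds ratios were 1.51 and 2.50 (Fisher's exact p = 0.00158 and p = 1.11e-18). With the replicate number as a block, 79 and 257 loci were called at 24 h and 72 h. Among them were 33 and 134 rising B2 loci, with odds ratios of 3.07 and 6.11. Whether libraries with the same number share an animal is not stated.

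**Figure D3:**
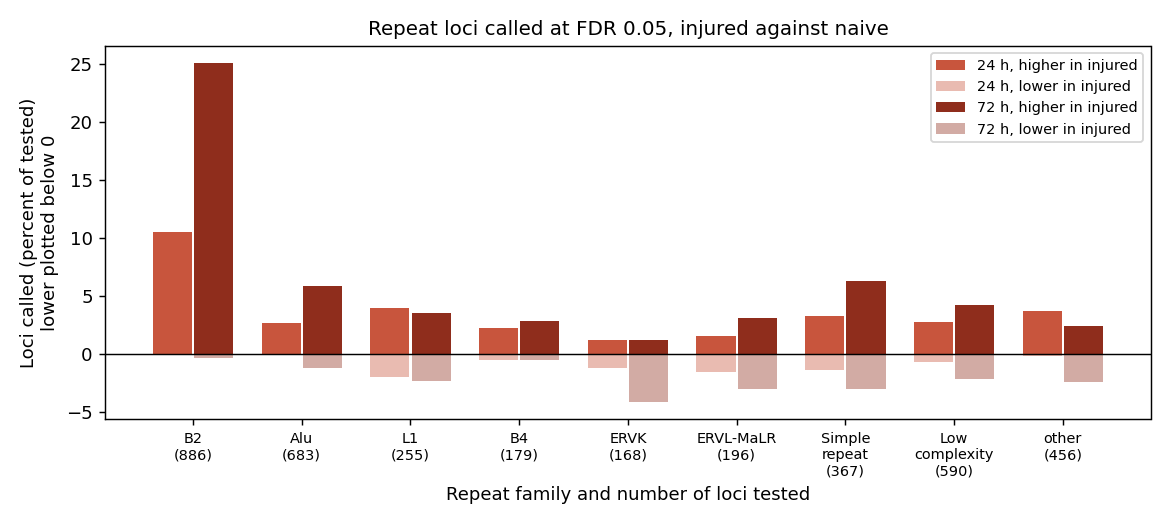
Percent of tested repeat loci (y axis) called higher (above 0) or lower (below 0) in injured ganglia at 24 h and 72 h, by repeat family with the number of tested loci (x axis). B2 stands at 10.5% and 25.1% higher, Alu at 2.64% and 5.86%.

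The largest B2 rises were at single copies with no count in any naive library of the same time. How reads shared between copies were counted is not given in the sources used here, so reads at a listed position may stem from other copies. At 72 h, a B3 copy of the B2 family on chromosome 6 (112208965 to 112208988, outside genes, 64.8 kb from Lmcd1) had 109 to 226 counts per injured library and 0 in naive ones, so it was at least 222-fold higher. Copies at chromosome 14 (64230379 to 64230402, B2_Mm1a, intron of Msra), chromosome 3 (78922515 to 78922538, B2_Mm2, outside genes) and chromosome X (51707663 to 51707686, B2_Mm2, outside genes) were at least 69.7-fold, 66.5-fold and 57.3-fold higher. At 24 h, the copies were on chromosome 14 (27326493 to 27326516, B2_Mm1t, intron of Arhgef3), chromosome 2 (69876278 to 69876301, B2_Mm1t, intron of Mettl5), chromosome 11 (101235656 to 101235679, B2_Mm2, outside genes) and chromosome 8 (33977567 to 33977605, B2_Mm2, outside genes). They were at least 39.3-fold, 33.1-fold, 28.5-fold and 27.3-fold higher. All these copies were picked by the size of their rise, which favors copies without naive counts. At the other time they did have naive counts, up to 10 per library for the 24 h copies and up to 6 for the 72 h copies. Fitted log2 fold changes at that other time were 2.97 to 4.405 for the 24 h copies and 4.115 to 6.21 for the 72 h copies. The 3 B2 loci that fell at 72 h lay in an intron of Snhg11 on chromosome 2 (158379216 to 158379239, log2 fold change −1.47), in an intron of Gm49353 on chromosome 10 (29203420 to 29203443, −0.90) and, named after its value was seen, in an exon of Cyld on chromosome 8 (88747831 to 88747854, −0.73, where Cyld itself fell by 0.47). In a count chosen after the values were seen, 14 B2 loci at 24 h and 22 at 72 h had at least 3 counts in each injured library and none in the naive libraries, and 0 B2 loci showed the reverse. Between the naive groups 1 B2 locus was seen only at 72 h and 0 only at 24 h.

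Single copies of other families had rises within the range of these. A copy of B1_Mus2, an Alu family element in an intron of Cda (chromosome 4, 138357238 to 138357261), was at least 126-fold higher at 72 h, and an L1 copy of type Lx6 outside genes on chromosome 5 (53800022 to 53800045) was at least 33.1-fold higher at 24 h and at least 83.9-fold at 72 h. A B4 window in an exon of Cop1 (chromosome 1, 159347145 to 159347168) was at least 27.7-fold higher at 24 h, but it had 14 to 29 counts in the naive and 0 to 10 in the injured libraries at 72 h. The falls at 24 h were a simple repeat in an exon of D130009I18Rik (chromosome 14, 104966391 to 104966414, −1.27) and an Lx copy of L1 (chromosome 17, 66256764 to 66256787, −1.25). Those at 72 h were endogenous retrovirus copies IAPEY4_I-int on chromosome 19 (8316936 to 8316959, −3.55, SE 1.01) and RLTR14 on chromosome 4 (156208147 to 156208170, −3.51, SE 1.005). The 2 retrovirus copies had few counts: 0 to 3 per injured library, against 5 to 24 and 8 to 34 per naive library.

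Summed over the family, B2 RNA was higher in injured ganglia at both times. At 24 h B2 windows had 1010 ± 270 CPM of scaled gene counts in injured and 736.3 ± 31.9 in naive libraries (SD, n = 4, fold 1.37, exact 2-sided permutation p = 0.0286). At 72 h the levels were 1384 ± 150 and 774.6 ± 79.4 (fold 1.79, exact 2-sided permutation p = 0.0286, the smallest this test can give). B2 windows in exons had near-equal levels (318.8 in injured and 327.0 in naive libraries at 24 h, exact permutation p = 0.429; 323.0 and 324.2 at 72 h, p = 0.857). B2 windows in introns went from 229.2 to 504.4 and those outside genes from 221.2 to 556.5 at 72 h (exact permutation p = 0.0286 for each). By subfamily the folds at 72 h were 2.74 for B2_Mm1t, 2.50 for B2_Mm2, 2.23 for B2_Mm1a, 1.45 for B3A and 1.31 for B3 (exact permutation p = 0.0286 for each but B3, p = 0.0571). At 24 h injured replicate 4 had a level of 1411, against 827 to 913 in the other injured libraries, and the fold without it was 1.19. Without any 1 of the naive 24 h libraries the 24 h exact permutation p was 0.0571. As CPM of the repeat table the 24 h fold was 1.06 (exact permutation p = 0.314), and as CPM of that table without rRNA windows it was 1.32 (exact permutation p = 0.0286). Whether the 72 h response exceeded the 24 h one depended on scaling. The log2 difference was 0.41 by gene counts (permutation p = 0.299 over 4900 relabelings), 0.66 as CPM of the repeat table (permutation p = 0.0273) and 0.34 as CPM of that table without rRNA windows (permutation p = 0.332). By edgeR, 0 B2 loci differed between the responses, with 87 at an unadjusted p under 0.05 and 5 by DESeq2.

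Among 37 families tested by edgeR, 3 passed at 72 h: B2 rose (log2 fold change 0.84, SE 0.14, adjusted p = 0.000569), scRNA rose by 0.23 (SE 0.05, adjusted p = 0.00431) and the retroviral ERVL-MaLR fell by 0.20 (SE 0.03, adjusted p = 0.000279). Alu did not pass the test (0.12, SE 0.05, adjusted p = 0.0919). At 24 h, B2 (0.46, SE 0.14), rRNA (1.14, SE 0.31), scRNA (0.17, SE 0.05) and hAT (0.64, SE 0.20) rose and ERVL-MaLR fell by 0.11 (SE 0.03), with adjusted p between 0.0424 and 0.0474. Without injured 24 h replicate 4, in which rRNA windows held 48.1% of repeat counts, 0 families passed at 24 h. The same was so with the replicate number as a block, without injured 24 h replicate 3 and without naive 24 h replicates 1 and 2. The counts were 3, 1 and 2 without injured 24 h replicates 1 and 2 and naive 24 h replicate 4. No family differed between the responses (4 at an unadjusted p under 0.05). Between the naive groups, srpRNA, the 7SL RNA of the signal recognition particle, was higher at 72 h by 0.80 (SE 0.15, adjusted p = 0.00355), and its windows in Rn7s1 and Rn7s6 and the Cop1 window were the 3 loci called there.

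**Figure D4:**
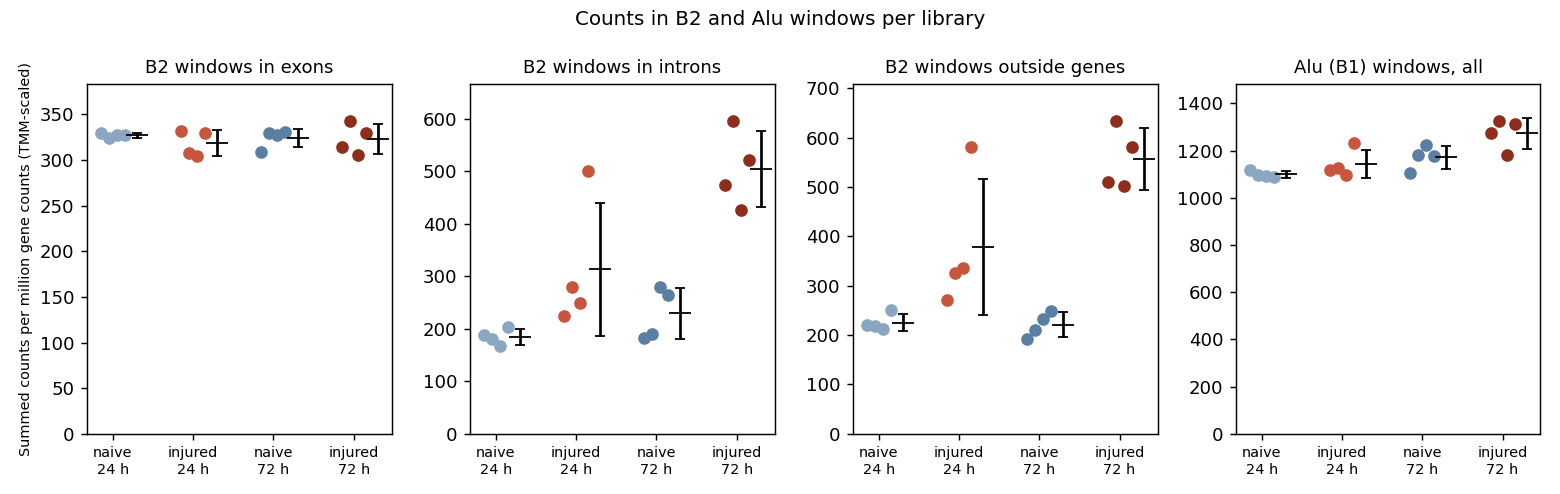
Summed CPM of scaled gene counts (y axis) in B2 windows of exons, introns and outside genes and in all Alu windows, for each library of the 4 groups (x axis), with mean and SD. At 72 h the injured libraries lie between 502 and 633 outside genes and the naive ones between 192 and 248.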

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

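The tests of intron and intergenic RNA, of host genes over all intron windows, of reads shared between copies, of immune cells, of a single library, of the naive level and of scaling were chosen after the results were seen; those of host genes at rising loci, nearest genes, neuron content and other splits of the libraries were written before.

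B2 windows were higher in injured ganglia at 72 h, and the first pattern weighed is whether this reflects B2 itself. More intron and intergenic RNA, or genomic DNA, would lift Alu and B2 windows alike. Outside exons, B2 rose over Alu by 0.831 on the log2 scale (SE 0.061, exact permutation p = 0.0286), B2 by 1.24 (SE 0.15) and Alu by 0.41 (SE 0.14). Such an excess therefore cannot be the whole cause. L1 windows outside exons changed by −0.20 (SE 0.05, exact permutation p = 0.0286), ERVK by −0.19 (SE 0.09) and B4 by 0.11 (SE 0.15). These values argue against an excess common to all these families, although a part shared with Alu stays open. Over all 27193 intron B2 windows of tested genes, called or not, B2 rose by 1.14 where the counts of the host genes predict 0.24 (SE 0.01). The difference was 0.899 (SE 0.19, exact permutation p = 0.0286), so host gene counts do not account for the whole rise. Unspliced RNA of the host genes was not measured separately, so a rise of it stays open. That 85 of 88 rising loci (96.6%) exceeded their host by over 2 SE decides nothing, as they were chosen for their rise. The nearest tested gene rose for 14 of 115 rising intergenic B2 loci (12.2%) against 39 of 240 others (16.3%, Fisher's exact p = 0.344), so rising loci were not found beside rising genes more often. Read-through from a gene whose own count did not rise was not tested. The younger B2_Mm copies rose over B3 by 0.861 (SE 0.068), but how reads shared between copies were counted is not stated, so a rise at each listed position and a rise at other copies cannot be told apart, and that the injury itself may raise B2 RNA is an untested hypothesis.

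Interferon response genes were higher at 24 h and not called higher at 72 h. As a list they were not called at 24 h with an estimated correlation (camera adjusted p = 0.0946). Without any single library, between 22 and 24 of these genes were still called higher at 24 h, so no single library carries the pattern. Immune cells in the injured ganglia may contribute: the highest rise of the 3 immune marker levels at 24 h was 0.359 (lymphocytes, SE 0.28, exact permutation p = 0.229), against 0.66 for the interferon list (SE 0.13, exact permutation p = 0.0286), and the spread of these markers leaves this open. In injured libraries the list level went down from 24 h to 72 h by −0.363 (SE 0.15, exact permutation p = 0.0571) and in naive libraries it went up by 0.29 (SE 0.05, exact permutation p = 0.0286), so a fading response and a higher naive level at 72 h cannot be told apart by these values. Time and library group are the same split here, which keeps both open.

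Ion channel and sensory identity genes were lower at 72 h. With an estimated correlation the ion channel list was called (camera adjusted p = 0.00375) and the sensory identity list was not (camera adjusted p = 0.0703). Fewer neurons in the injured preparations would lower all neuronal genes alike, but the pan-neuronal level changed by −0.08 (SE 0.023), against −0.46 (SE 0.04) for channels and −0.30 (SE 0.05) for sensory identity genes. Library scaling would shift both alike, yet the pan-neuronal change lay above that of the channels by 0.384 (SE 0.04) and above that of the sensory genes by 0.22 (SE 0.04). Among other cell types, macrophage markers differed by 0.90 (SE 0.36), neutrophil markers by −1.20 (SE 0.64), and satellite glia (−0.01, SE 0.10) and Schwann cells (0.04, SE 0.21) by less, which is not the common rise that a lower share of neurons would give. A loss of 1 class of sensory neuron from the preparation was not tested, so lower expression per neuron after injury is a hypothesis.

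Other splits of the same libraries tested whether chance can give such counts. For genes, the labelled split was the 1 of 35 with the largest count at 24 h (3641, highest other 72), at 72 h (5332, highest other 0) and between naive groups (448, highest other 17). It also had the largest count for loci (196 against 27 at 24 h, 409 against 0 at 72 h), for families at 72 h (3 against 0) and for rising B2 loci (93 and 222, each against 0). A first rank among 35 splits is the most that this test can show. The other splits mix the compared groups, which widens the spread within groups and lowers their counts, so a first rank does not exclude chance. For families at 24 h the labelled split was also the 1 of 35 with the largest count, but at 5 against 3 it was close to another, and 0 families passed without injured 24 h replicate 3 or 4 or naive 24 h replicate 1 or 2. Of 80 random regroupings for the difference of responses, the labelled one was the 1 with the largest count of genes (1207) and of loci (10). The highest others reached 1087 genes and 9 loci. The 2 times were regrouped separately, so a regrouping can keep the true labels at 1 time and carry the injury effect of that time into the difference. Which regroupings did so was not examined, so these counts do not decide whether chance gives such a difference. For the overlap the highest other was 8 against 2350. The number of called lists under the preset correlation was not above chance. At 24 h, 14 of 35 splits called as many lists as the 9 (highest other 13), and at 72 h 16 of 35 as many as the 10 (highest other 14). The same was so for 50 of 80 regroupings for the 8 lists of the difference (highest other 15), and for 2 of 35 splits for the 14 lists between naive groups (highest other 16).

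The responses at the 2 times differed by the interaction test at 1207 genes and 10 repeat loci. The ion channel list differed with a median of −0.314. None of the 10 loci was B2; they were named after their values were seen, and include exon windows of Car3 (4.17), Bdnf (−1.82), Stmn2 (0.78) and Areg (−3.26) and 4 rRNA windows.

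Among 104 groups of 4 libraries tested for a library far from the others, 3 had one, where chance gives about 5 in 100. Injured 24 h replicate 4 had the highest summed B2 level (1411 against 827 to 913, gap over range 0.853). For immediate-early and heat-shock genes, naive 24 h replicate 4 had the lowest level (5.32 against 5.50 to 5.53, gap over range 0.839) and injured 24 h replicate 3 the highest (5.70 against 5.43 to 5.47, gap over range 0.835).

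The windows without a repeat family, which no comparison used, also changed. Of 10056 tested by edgeR, 245 were called at 24 h (192 higher, 53 lower) and 513 at 72 h (303 higher, 210 lower). Of those in a tested gene, 234 of 237 and 504 of 504 had the sign of that gene.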

How the results depend on the processing

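The covariate of erythroid and neutrophil marker level, B2 outside exons or relative to repeat counts without rRNA, and leaving out libraries for lists, overlap and B2 share were chosen after seeing the data. Gene counts at 24 h and 72 h stayed within 1.5 times of the reported ones in every alternative run, from 2716 to 4335 and from 4304 to 6116, and for the difference of responses from 841 to 1692. Of the 3641 and 5332 calls, 99.8% and 99.6% were also called in the same direction by DESeq2. The lowest shares kept were 74.1% at 24 h, with only the groups compared, and 76.5% at 72 h, with the marker covariate. B2 odds ratios stayed above 1 and past the threshold, but with at least 10 counts in total they were 1.506 and 2.498, against 4.02 and 7.66. Values for named genes stayed on their side in all 560 alternatives, and for named loci in 193 of 240, with 47 weaker. List values did so in 999 of 1122 (80 weaker, 41 stronger) and family values in 80 of 120 (39 weaker, 1 stronger).

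With a minimum log2 fold change of 1, 320 genes overlapped, which follows from fewer genes. Called lists with an estimated correlation were 3 at 24 h, 4 at 72 h, 1 for the difference and 0 between naive groups. With the marker covariate, 9 lists were called between naive groups and 219 loci at 72 h, and the naive list medians of macrophage and erythroid markers turned to −0.388 and −0.105, as the covariate holds erythroid markers; for macrophages the cause was not tested. Genes between naive groups numbered 1168 with no filter and 948 by DESeq2. DESeq2 called 324 loci at 24 h and 35 for the difference. A minimum total of 10 counts gave 62 loci for the difference, and a mean of at least 20 counts gave 98 and 219 loci at 24 h and 72 h, where fewer loci were tested. Families at 24 h numbered 3 under their own scaling. As CPM of the repeat table the 24 h B2 fold was 1.064 (exact permutation p = 0.314), as rRNA windows held 35.2% of repeat counts in injured and 21.3% in naive libraries; without them it was 1.32 (exact permutation p = 0.0286). The cause was not tested for the others.

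Replicate numbers did not pass the check for pairing: same-numbered injured and naive libraries correlated at 0.047 to 0.101 after removal of group means, where all had to exceed 0.1, although 15 of 16 libraries correlated best with their own number. At 24 h each same-number correlation (0.047 to 0.088) lay above every other one (at most 0.026). Missing the cut-off of 0.1 thus does not show that the numbers are unpaired, and pairing stays open. With the number as a block, genes were 4335 and 5954, loci 79 and 257 (33 and 134 of them rising B2 loci, against 93 and 222), and families at 24 h 0; the B2 folds 1.372 and 1.787 had an exact sign-flip p = 0.125, the smallest 4 pairs allow. The naive comparison cannot be blocked.

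Leaving out 1 library gave 170 to 391 genes and 9 to 15 lists between naive groups (9 without naive 24 h replicate 3), 97 to 189 loci and 0 to 4 families at 24 h, 248 to 330 loci at 72 h, and a 24 h B2 fold of 1.190 to 1.454. Without a naive library its exact permutation p was 0.0571. In simulation at the depth and group size of these libraries, a fold of 2 was recovered at 28.4% and 10.4% of loci at 24 h and 72 h.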

Other observations

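Glial markers changed in single genes rather than as lists. All marker values are those of cells left after dissociation and the Percoll step, which may differ from the cells of the intact ganglion. Of 18 satellite glial markers, 3 rose and 4 fell at 24 h (4 and 4 adjusted over the list alone; adjusted p = 0.979 with an estimated correlation). The glutamine synthetase gene Glul rose by 0.46 (SE 0.05), the filament gene Gfap by 4.28 (SE 0.57), and the potassium channel gene Kcnj3 fell by 0.55 (SE 0.08). At 72 h, 3 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.931 with an estimated correlation). Of 16 myelinating Schwann cell markers, 2 fell at 24 h, Mbp (log2 fold change −0.54, SE 0.16) and Drp2 (−0.42, SE 0.14), and 3 rose at 72 h, among them Gldn (1.90, SE 0.21) and Pmp22 (0.21, SE 0.07). The lists were not called (adjusted p = 0.893 and 0.985 with an estimated correlation). Endothelial (2 of 14 rose, adjusted p = 0.893), mural (1 of 9 fell, adjusted p = 0.892), and fibroblast (0 of 14, adjusted p = 0.893) markers were not called at 24 h with an estimated correlation, nor were macrophage (0 of 24, adjusted p = 0.893), neutrophil (0 of 13, adjusted p = 0.893), lymphocyte (1 of 10 rose, adjusted p = 0.893) and erythroid (0 of 6, adjusted p = 0.893) markers. At 72 h, 1 endothelial, 2 mural and 1 erythroid marker fell, and 0 lymphocyte and 0 fibroblast markers changed by edgeR.

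None of the following lists passed with an estimated correlation at the times given. Of 32 ribosome biogenesis genes, 8 rose at 24 h and 11 rose and 1 fell at 72 h (10 and 13 rose adjusted over the list alone; camera adjusted p = 0.0356 and 0.0417 with the preset correlation; adjusted p = 0.436 and 0.435 with an estimated correlation). They include Nop58 (0.65, SE 0.08 at 24 h) and Rrp12 (0.70, SE 0.09 at 72 h). The 72 h count of rises was 6, 7 and 7 without injured 72 h replicates 2 and 3 and naive 72 h replicate 4. Of 26 RNA polymerase III genes, 5 rose at 24 h and 7 rose and 1 fell at 72 h (5 and 8 rose adjusted over the list alone; adjusted p = 0.893 and 0.723 with an estimated correlation). Of 35 retrotransposon silencing genes, 5 rose at 24 h, and 5 rose and 2 fell at 72 h (5, and 4 and 1, adjusted over the list alone; adjusted p = 0.475 and 0.931 with an estimated correlation). Resf1 rose by 0.71 (SE 0.08) and by 0.50 (SE 0.08), and the DNA methyltransferase gene Dnmt3a fell by 0.45 (SE 0.08) at 72 h. Of 25 proliferation genes, 1 rose at 24 h, Prc1, a midzone microtubule protein gene, by 1.24 (SE 0.12), and at 72 h by 2.23 (SE 0.11); 2 rose and 4 fell at 72 h (adjusted p = 0.985 with an estimated correlation). Of 21 immediate-early and heat-shock genes, 3 rose at 24 h, Hspb1 (0.77, SE 0.09), Arc (0.88, SE 0.135) and Ier3 (0.31, SE 0.08), and 3 rose and 7 fell at 72 h (adjusted p = 0.893 and 0.931 with an estimated correlation). Of 23 inflammatory genes, 6 rose and 1 fell at 72 h (camera adjusted p = 0.00805 with the preset correlation; adjusted p = 0.435 with an estimated correlation). Of 24 cholesterol synthesis genes, 7 rose at 24 h (camera adjusted p = 0.0114 with the preset correlation; adjusted p = 0.629 with an estimated correlation).

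A hypothesis formed, and a test chosen, after the B2 result was seen was that the B2 rise is part of a general rise, as large as that of B2, of transcripts made by RNA polymerase III. Of 9 other families and genes transcribed by this polymerase, 1 was called higher at 72 h by edgeR, the scRNA family, by 0.233 (SE 0.05), and 2 had an unadjusted p under 0.05. The 9 are not independent, as the srpRNA family and the genes Rn7s1, Rn7s2 and Rn7s6 all count 7SL RNA. Alu was taken with its exon windows (0.12, SE 0.05). Outside exons Alu rose by 0.41 (SE 0.14) and B2 by 1.24 (SE 0.15). Each of the 9 lay below the B2 rise of 0.84 (SE 0.14) by over 2 SE, which argues against a rise of that size common to these 9. The snRNA family was not among the 9. It rose by 0.64 (SE 0.23) at 72 h without being called by edgeR (adjusted p = 0.0789), and its windows were not divided by polymerase. A smaller general rise stays open. How well such short RNAs were captured was not measured, which limits the test.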
